A study of Mus musculus with 2 samples.

How the data were processed

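Live spleen cells of anaemic mice were profiled by droplet-based single-cell RNA sequencing, with 1 library for chronic PHZ treatment and 1 for chronic bleeding. The number of mice in each library and any removal of mature red cells were not stated. The deposited matrices hold counts: whole UMI counts per gene and barcode, for all barcodes including empty droplets, with no normalisation. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 7.0.0 against mouse build mm10, while the header of the matrices names version 4 of that software; the annotation release and the handling of intronic reads were not stated. Both files list the same 32285 genes, of which 32158 matched GENCODE M21 by identifier, used for GRCm38 positions. The PHZ matrix held 128130213 UMIs over 1608470 barcodes and the bleeding matrix 145260780 UMIs over 1698351.

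All choices of filters, classes, lists, comparisons and alternatives were fixed before the data were examined, except those named below as added later. A barcode was called a cell with at least 1000 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Of 9429 and 13075 barcodes with 1000 or more UMIs, 2618 and 3047 had under 300 genes and 6445 and 9707 passed all filters. Doublets were scored per library with Scrublet in scanpy 1.11.5 (expected rate 0.06), and the highest-scoring 0.8% per 1000 cells were removed, 332 and 754. The cells kept, 6113 and 8953, held 86959296 and 91828908 UMIs, which are 67.9% and 63.2% of each matrix; the median cell had 1858 and 2245 genes and 1.18% and 3.08% mitochondrial UMIs. Haemoglobin genes took 44.4% and 32.3% of UMIs in cells, and 40.5% and 33.5% in the background barcodes of 10 to 100 UMIs.

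Cells of both libraries were clustered together: counts scaled to 10000 per cell and log transformed, 2000 variable genes, 30 principal components, 15 neighbours, a shared-neighbour graph and Leiden clustering at resolution 1 with seed 0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Immunoglobulin, T cell receptor, haemoglobin, mitochondrial, ribosomal protein and sex-linked genes were left out of the variable genes. A cluster took a class name from fixed markers if at least 3 were among its 50 leading genes and its first 10 genes favoured no other class. Rules that left a cluster without a name were added after the data were seen: at least 2 precursor B cell genes, at least 3 germinal centre genes, or T cell CD3 genes in an NK cell-like cluster. Erythroid stages, red pulp macrophages and monocytes without them were treated as parts of the erythroid and the monocyte or macrophage classes; their use as separate groups for expression was added later. Shares were given with exact Clopper-Pearson 95% intervals.

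For expression, UMIs were summed over the cells of a class in each library and scaled to the class total without haemoglobin genes (CPM). Classes with at least 100 cells in each library were compared: erythroid, B, T, neutrophil and monocyte or macrophage. Parts of these classes were compared too, and early progenitor-like cells (77 bleeding cells) and monocyte-like cells (71 bleeding cells) are below that minimum. Ratios carry exact conditional 95% intervals for counting error; cells were not treated as replicates, and no test between treatments was made, since each group had 1 library. The totals without haemoglobin were 25174712 and 11648016 UMIs for erythroid-like cells and 1943888 and 1760572 for monocyte or macrophage-like cells. Where a library had 0 UMIs, the ratio was computed against a floor of 3 counts over the group. Gene lists, 39 in all, were summarised by the median log2 ratio of members with a mean of at least 10 CPM, where at least 5 were measured, with the percentile among 10000 random lists of the same size matched on expression in 20 bins, as a description and not a test. The counts of members over 1 count any ratio above 1.

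Named genes had at least 50 UMIs and 50 CPM in the higher library, at least 20% of the highest class level of that library, and belonged to none of the gene groups left out of clustering. They were ranked by the interval bound nearest 1, and the first 12 per direction (erythroid, monocyte or macrophage, and their parts) or 6 (other classes) were named where that bound was beyond 1.5-fold. Members named from a list were among the 4 with the most UMIs or had a bound beyond 2-fold. The value of 1 such member is not reported here.

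The comparison was tested on simulated data, with counts drawn from the same class totals and 200 genes altered. In erythroid-like cells, 95.6% of intervals over 12051 genes covered the true ratio, and the rule named 4.48% of 67 genes altered 1.5-fold, 100% of 67 altered 2-fold and 100% of 66 altered 4-fold. In monocyte or macrophage-like cells the interval coverage was 96.1% over 9698 genes and the rule named 0%, 68.7% and 100% of those genes. In T cell-like cells the coverage was 96.0% over 12161 genes and the rule named 2.99%, 100% and 98.5%. It named 0 of the 11722, 9379 and 11807 unaltered genes. Counts drawn from class totals hold no spread between cells, mice or libraries. The coverage and the 0 unaltered genes named therefore apply to counting error only. They do not show how the intervals or the rule perform on the real libraries, where a few cells held most UMIs of some genes.

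Alternatives fixed in advance were minimums of 500 and 2000 UMIs, mitochondrial limits of 5% and 20%, no doublet removal, Leiden resolutions 0.5 and 2, all UMIs as the denominator, median-of-ratios scaling, each cell scaled to the same total, subtraction of a background profile, and list members by 50 CPM or by 1 UMI in both libraries. Added after the data were seen were a gene minimum of 50 per barcode, shares among cells outside the erythroid-like class, leaving out the low-UMI clusters 15 and 20 or the haemoglobin-rich B cell-like cluster 30, and leaving out the 3 cells with most UMIs of a gene. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.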

Results

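The deposited data were droplet-based single-cell RNA counts from the spleens of mice made anaemic for 1 month, by PHZ injection or by bleeding every 3 days. The comparison addressed how spleen cells differ between these forms of chronic anaemia. Each treatment had 1 library, and untreated mice were not analysed here. After filtering, the PHZ library held 6113 cells with a median of 12242 unique molecular identifiers (UMIs), and the bleeding library held 8953 cells with a median of 8045. Ratios are PHZ over bleeding, and intervals are 95% intervals that cover counting error only. With 1 library per group no test between treatments was possible, and a difference between treatments could not be separated from a difference between mice or between libraries. Cell classes are named by their marker genes with "-like".

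Red cell precursors formed the largest class in the PHZ library, while B cells did so in the bleeding library. That order turned in the bleeding library when barcodes with at least 50 genes were admitted, with 45.4% erythroid-like and 25.7% B cell-like cells. Erythroid-like cells were 54.7% of cells (53.4 to 55.9) in the PHZ library and 27.1% (26.1 to 28.0) in the bleeding library. The ratio was 2.02 (1.92 to 2.13). B cell-like cells were 23.7% and 37.3%, and T cell-like cells were 7.51% and 21.7%. Their ratios were 0.635 (0.596 to 0.675) and 0.347 (0.312 to 0.384). Neutrophil-like cells were 4.83% in the PHZ library and 1.24% in the bleeding library, a ratio of 3.89 (3.12 to 4.89). Monocyte or macrophage-like cells made up similar shares, 2.80% and 3.16%, but were different cells. Red pulp macrophage-like cells, which recycle iron from old red cells, numbered 17 and 212, and the remaining monocyte-like cells numbered 154 and 71. Their ratios were 0.117 (0.0671 to 0.193) and 3.18 (2.38 to 4.27), and the first was 0.0618 with a minimum of 2000 UMIs per barcode.

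Shares of all cells depend on the erythroid-like share, so the other classes were also compared among the cells outside it, 2770 and 6530. There, B cell-like cells had a ratio of 1.02 (0.960 to 1.09), the opposite direction to their share of all cells, and T cell-like cells stayed lower in the PHZ library at 0.558 (0.503 to 0.618). Neutrophil-like cells were at 6.27 (5.02 to 7.87), monocyte-like cells at 5.11 (3.84 to 6.87) and red pulp macrophage-like cells at 0.189 (0.108 to 0.310). The whole monocyte or macrophage-like class went from 0.885 among all cells to 1.42 outside the erythroid-like class, and dendritic cell-like cells from 0.822 to 1.32. NK cell-like cells were 0.608 among all cells (0.449 to 0.815) and 0.979 outside the erythroid-like class. Plasma cell-like cells numbered 8 and 46, a ratio of 0.255 (0.104 to 0.545) among all cells and 0.410 outside the erythroid-like class, and 0.753 of all cells when barcodes with at least 50 genes were admitted. Basophil or mast cell-like cells numbered 6 and 9. Clusters without a name held 3.63% of PHZ cells (3.18 to 4.13) and 5.29% of bleeding cells (4.84 to 5.78), a ratio of 0.686 (0.582 to 0.806) that was 1.10 (0.937 to 1.30) outside the erythroid-like class.

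**Figure D1:**
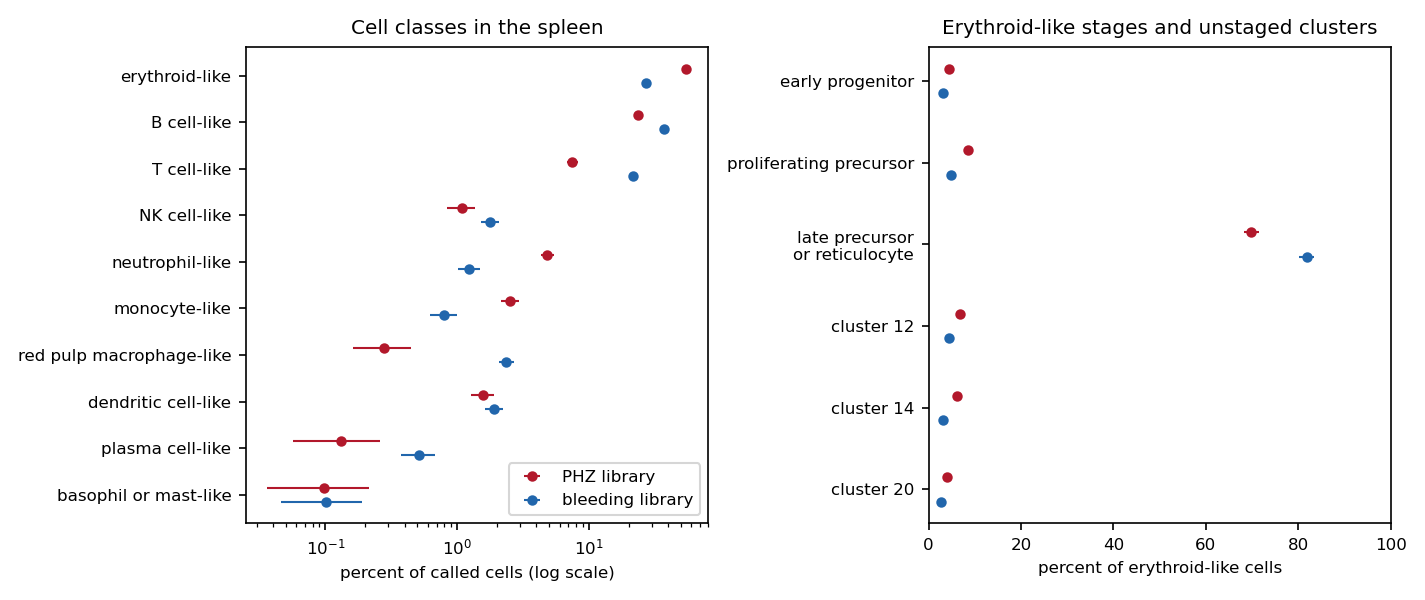
Percent of called cells per class (left, log scale) and percent of erythroid-like cells per stage or unstaged cluster (right), with points for the PHZ (red) and bleeding (blue) libraries and bars for 95% counting intervals. Erythroid-like cells were 54.7% and 27.1% of called cells, and late erythroid-like cells 69.8% and 81.8% of erythroid-like cells. The B cell-like, monocyte or macrophage-like and dendritic cell-like ratios turn direction outside the erythroid-like class. The B cell-like interval there spans no difference, as do the monocyte or macrophage-like and dendritic cell-like intervals among all cells.

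Within the erythroid-like class of the PHZ library, proliferating precursors took a larger share and late cells a smaller share. Early progenitor-like cells were 4.43% and 3.18% of erythroid-like cells, a ratio of 1.39 (1.05 to 1.86). It was between 1.08 and 1.33 under 6 of the alternatives, all with intervals that cover 1, and 4.25 when barcodes with at least 50 genes were admitted. Proliferating precursor-like cells were 8.64% and 4.87%, a ratio of 1.78 (1.43 to 2.22), and 3.05 at clustering resolution 2. Late precursor or reticulocyte-like cells were 69.8% and 81.8%, a ratio of 0.854 (0.804 to 0.907), although they numbered 2334 and 1981, more in the PHZ library. The late cells of both libraries shared the same clusters in different shares. Cluster 2 held 38.4% of the bleeding erythroid-like cells and 15.7% of the PHZ ones, a ratio of 0.409 (0.367 to 0.455), while cluster 3 was at 1.07 and cluster 6 at 1.43. The unstaged clusters 12, 14 and 20 had ratios of 1.56, 1.96 and 1.55. Adult globins took most erythroid-like UMIs in both libraries, with Hbb-bs at 27.8% and 32.8% and Hba-a2 at 9.43% and 11.2%. Embryonic globins had few UMIs, 20 and 28 of Hbb-y and 2 and 28 of Hbb-bh1.

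The genes higher in PHZ erythroid-like cells included Cish and Erfe, which erythropoietin induces. Cish, an inhibitor of cytokine signalling, was at 87.6 CPM (counts scaled to the class total without haemoglobin genes) in the PHZ library and 33.2 in the bleeding library. Its ratio was 2.64 (2.37 to 2.94). Erfe, the hormone by which erythroblasts suppress hepcidin, had a ratio of 2.24 (2.01 to 2.51), and Mthfd2, a mitochondrial folate enzyme, 1.84 (1.73 to 1.96). The others named were Ankrd36 (2.59), the lysosomal enzyme gene Gusb (2.37), Ccdc189 (2.33), the volume-regulated anion channel gene Lrrc8b (1.90), Xbp1 of the unfolded protein response (1.89), Tsc22d2, the thromboxane synthase gene Tbxas1, Apol8 and 1810037I17Rik, down to 1.71. Among the genes lower in the PHZ library, Bpgm, which makes the 2,3-bisphosphoglycerate that loosens oxygen from haemoglobin, was at 0.491 (0.486 to 0.495). The ubiquitin genes Ubb and Ube2b were at 0.575 (0.570 to 0.580) and 0.546, and Mkrn1, a ubiquitin ligase gene, at 0.571. Cd36, a scavenger receptor, was at 0.492, the peptide transporter gene Slc15a2 at 0.329 (0.294 to 0.367) and Jund, a transcription factor, at 0.529. Fam220a, Gm10371, Plaat3 and Ccndbp1 were between 0.510 and 0.562. Bpgm, Fam220a and Mkrn1 are leading genes of the late cluster 2, whose share of erythroid-like cells had a ratio of 0.409. They also lead the late cluster 3, at 1.07, and Bpgm and Mkrn1 lead the late cluster 8, at 1.48. These cluster ratios are of cell shares. By UMIs without haemoglobin, late cells held 4940402 of 25174712 in the PHZ library and 3068494 of 11648016 in the bleeding library. That is a smaller part in the PHZ library, which lowers genes of late cells in the class sums. Within late erythroid-like cells Bpgm was at 0.643. With barcodes of at least 50 genes admitted, Bpgm was at a log2 ratio of -1.67 against -1.03, and Mkrn1 at -1.56 against -0.81. Fam220a, Jund, Gm10371, Ube2b, Plaat3 and Ccndbp1 were then between -1.49 and -1.77. With each cell scaled to the same total, Gusb, Lrrc8b and 1810037I17Rik were at log2 ratios of 2.09, 1.58 and 1.65. Angpt1, a ligand made by stem and progenitor cells, was at 0.104 (0.0864 to 0.125), but 3 cells held 86.0% of its bleeding UMIs; without the 3 highest cells in each library it was 0.266, and with barcodes of at least 50 genes it turned to a log2 ratio of 2.25.

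**Figure D2:**
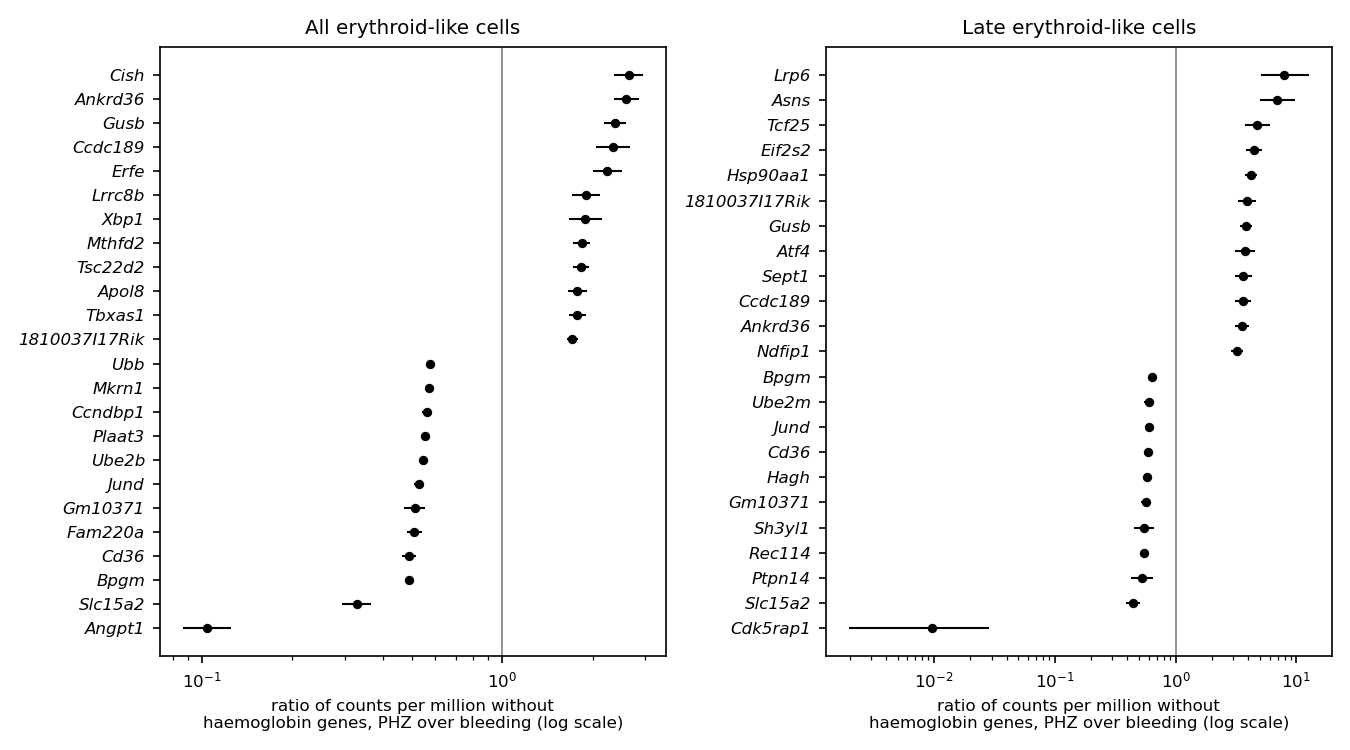
Ratio of CPM without haemoglobin genes, PHZ over bleeding (log scale), for the genes named in all erythroid-like cells (left) and in late erythroid-like cells (right), with bars for 95% counting intervals. Cish is at 2.64 and Bpgm at 0.491 on the left, and Asns at 6.95 on the right; Angpt1 rests on few cells and turns direction with a minimum of 50 genes per barcode.

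The fixed gene lists were compared in erythroid-like cells. Class sums weight each cell by its UMIs. Of 25174712 PHZ and 11648016 bleeding UMIs without haemoglobin, the 148 and 77 early progenitor-like cells held 9794824 and 5056608. The 2334 and 1981 late cells held 4940402 and 3068494. The values below therefore describe early cells more, and late cells less, than their shares of cells. The median log2 ratio of all genes was 0.01, and it shifted by 0.42 with all UMIs as the denominator, by 0.27 with each cell scaled to the same total and by 0.55 with barcodes of at least 50 genes. Alarmins and acute phase had the highest median here, 0.43 (5 of 9, mean 0.098, percentile 100), with S100a8 at 1.80 and Ifitm3 at 0.887, but turned to -0.036 with barcodes of at least 50 genes. In late erythroid-like cells they were at 0.58 (9 of 11), with S100a8 at 1.91. S100a8 is a gene of neutrophil-like cells, whose share was higher in the PHZ library, and background RNA was not ruled out for it. The erythropoietin and stress erythropoiesis list had a median of 0.21, with 6 of 10 members over 1 and a percentile of 99.0 among random lists. In it, Tnfrsf13c was at 3.97 (3.12 to 5.11), Pim1, a survival kinase gene, at 1.34, Epor, the erythropoietin receptor gene, at 1.06 and Bcl2l1 at 0.857. It was -0.05 with all members of 1 or more UMI. The integrated stress response list was at 0.16 (10 of 14, percentile 96.5), with Atf4 at 1.35 and Eif2ak1, the haem-regulated kinase gene, at 1.08; its median was 1.23 with each cell scaled alike. Haem synthesis was at 0.14 (10 of 14, percentile 95.4), although the sum of its members went the other way at 0.935. Alas2, the first enzyme, was at 0.689 and the ferrochelatase gene Fech at 0.794. Both are markers of the late stage, which held a smaller part of the class UMIs in the PHZ library. The red cell membrane list was at 0.21 (17 of 19, percentile 100), with Ank1 at 1.28 and Slc4a1 at 1.09. Erythroid transcription factors were at 0.15 (11 of 17, percentile 96.8), with Tal1 at 1.34, and the NRF2 antioxidant list at 0.14 (16 of 24, percentile 98.4), with Gpx1 at 1.14. Cell cycle lists were a little higher, S phase at 0.14 (39 of 42) and G2 and M phase at 0.15 (44 of 51). So were oxidative phosphorylation at 0.17 (30 of 36) and ribosomal proteins at 0.087 (68 of 79). Heat shock genes were at 0.10 (10 of 15), but the interval of that median over its members spanned no difference. With barcodes of at least 50 genes the integrated stress response, heat shock and S phase medians were 0.76, 0.70 and 0.83.

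A second set of lists went lower or split by abundance in erythroid-like cells. Autophagy and organelle clearance had a median of 0.029 (8 of 15) but a mean of -0.12 and a ratio of sums of 0.762, and turned to -0.33 with barcodes of at least 50 genes. Its most abundant members were lower. Bnip3l, which clears mitochondria from reticulocytes, was at 0.573, Ube2l6 at 0.638 and Map1lc3b at 0.696. Bnip3l and Ube2l6 are also markers of the late stage. Late cells held a smaller part of the class UMIs without haemoglobin in the PHZ library, so the mix of stages lowers such genes too. The proteasome and ubiquitin list likewise had a median of 0.12 (28 of 33, percentile 93.5) against a ratio of sums of 0.790, set by Ubb, and a median of 0.75 with each cell scaled alike. Glycolysis was at -0.028 (4 of 14) with a ratio of sums of 0.590, set by Bpgm, and turned to 0.39 with all UMIs as the denominator and to 0.30 with each cell scaled alike. Hypoxia inducible factor targets were at -0.0043 (7 of 16), with a mean of 0.025, and turned to 0.42 and 0.38 under the same scalings. Iron uptake and storage was at -0.019 (7 of 14) and turned to 0.37 and 0.27, with Ftl1 at 0.900 and Fth1 at 1.11. The type I interferon list was at -0.19 (3 of 18, percentile 0), with Ifi27l2a at 0.193 and Isg15 at 0.881, and at 0.25 with all UMIs and 0.19 with each cell scaled alike. Those scalings put the median of all genes at 0.44 and 0.28, so the interferon list stayed below the other genes and its change of sign came with the scaling. The glycolysis, hypoxia and iron uptake medians lay near those of all genes under them, so their changes of sign came with the scaling too. Complement, scavenging and efferocytosis was at -0.32 (1 of 7, percentile 0.20), with Cd36 at 0.492 and Ctsb at 0.801, and at -1.40 with all members of 1 or more UMI. The interferon gamma and MHC class II list was at -0.38 (4 of 16) and turned to 0.04 with all UMIs, below the 0.44 of all genes. Its lowest abundant members were the B cell genes Cd74 (0.247) and H2-Aa (0.272). Immunoglobulin constant regions were at -2.24 (0 of 8), with Igkc at 0.146 and Jchain at 0.111, and between -1.46 and -2.94 under the cell filters. They moved with the lower B and plasma cell-like shares of the PHZ library.

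The earlier erythroid stages were compared in the same way. In proliferating precursor-like cells, the erythropoietin and stress erythropoiesis list had a median of 0.80 (6 of 8, percentile 100), with Tnfrsf13c at 3.91 (2.62 to 6.08), Erfe at 1.97 (1.65 to 2.37), Pim1 at 1.53 and Epor at 0.792; it was 0.10 with all members of 1 or more UMI. Cish was at 2.12 (1.76 to 2.57), Mthfd2 at 2.24 (1.83 to 2.75), Selenow at 2.28 and Tsc22d2 at 2.03. Cd36 was at 0.485, Cacna1g at 0.453 and Trmo at 0.421. Ribosomal protein genes were at 0.48, higher in 79 of 79, led by Rps2 at 1.85. Type I interferon genes were at -0.48, higher in 0 of 15, with Ifitm3 at 0.401. The remaining named genes of this stage (higher: Gusb, Cacna1c, Ankrd36, Prpf6, Lrrc8b, Gm42047, Gm32051; lower: Wwox, Fam107b, Thsd7b, Bst2) moved by over 1.5 times with the cell filters. Gusb went from a log2 ratio of 2.24 to 1.07 with a minimum of 500 UMIs, and Wwox from -1.85 to -0.28 with a minimum of 2000. In early progenitor-like cells Pkhd1l1 was at 1.87 (1.57 to 2.24) and Rnf220 at 0.519. The log2 ratio of Pkhd1l1 was 0.90, and 0.18 with a minimum of 500 UMIs. Mpo, Ctsg and Prtn3, which encode granule proteins of myeloid precursors, had 3, 4 and 16 UMIs against 463, 288 and 358, with nearly all of the bleeding UMIs in 1 cell. Prtn3 turned to a log2 ratio of 1.20 without the 3 highest cells. Angpt1 (0.112), Pcdh7 (0.430) and Cmtm7 (0.444) were lower too, but with barcodes of at least 50 genes their log2 ratios were 1.46, -0.42 and 0.04.

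In late erythroid-like cells, the integrated stress response and heat shock lists were both higher in the PHZ library. The integrated stress response median was 1.47, with 12 of 12 members over 1 and a percentile of 100, and the heat shock and protein folding median was 1.52 (16 of 17, percentile 100), against 0.16 for all genes. Among the stress response genes, Atf5 was at 10.9 (5.96 to 22.2), Asns, the asparagine synthetase gene, at 6.95 (5.05 to 9.82), Ddit3, which encodes CHOP, at 6.50 (3.67 to 12.5). Atf4, their shared regulator, was at 3.74 (3.09 to 4.55), Mthfd2 at 2.88 and Ppp1r15a at 1.14. Among the chaperones, Hspa1a had 181 UMIs in the PHZ library and 0 in the bleeding library, at least 37.5-fold higher against a floor of 3 counts. Hspa1b was at 17.0 (7.12 to 53.2), Hsp90aa1 at 4.20 (3.78 to 4.69), Hspa8 at 2.88 and Hsp90ab1 at 2.87. The 3 highest PHZ cells held 19.1% of the Hsp90aa1 UMIs there. Without the 3 highest cells in each library Hsp90aa1 was at 4.01. How many cells held the Hspa1a and Hspa1b UMIs was not checked. The list medians depended on the settings. The integrated stress response was 0.71 with all UMIs as the denominator and 0.53 with members of 50 or more CPM. Heat shock was 0.80 without doublet removal, 0.92 with barcodes of at least 50 genes and 0.72 with all members of 1 or more UMI. The all-gene median of this stage shifted by 0.34 with all UMIs, 0.14 with at least 50 genes, 0.11 after background subtraction and -0.16 under median-of-ratios scaling.

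Other late erythroid-like genes went both ways. Eif2s2, a subunit of the initiation factor that the integrated stress response blocks, was at 4.46 (3.87 to 5.18). Lrp6, a Wnt co-receptor gene, was at 7.85 (5.08 to 12.7), a log2 ratio of 2.97, and Tcf25 at 4.76, a log2 ratio of 2.25. Without doublet removal their log2 ratios were 1.97 and 1.59. Sept1, Ccdc189, Ankrd36, Gusb, 1810037I17Rik and Ndfip1 were between 3.21 and 3.88. Cdk5rap1, which modifies mitochondrial transfer RNA, had 3 and 194 UMIs, a ratio of 0.00960 (0.00196 to 0.0285), with log2 ratios from -5.19 to -8.02 over the alternatives. Slc15a2 was at 0.447, with Bpgm, Cd36, Jund, Ptpn14, Rec114, Sh3yl1, Gm10371, Hagh and Ube2m between 0.524 and 0.643. The unfolded protein response list was at 0.74 (13 of 15), with Xbp1 at 2.31 and the plasma cell gene Mzb1 at 0.210, and the NRF2 list at 0.47 (16 of 21). The proteasome list was at 0.73 (31 of 32), with Psma2 at 1.65, although its sum went the other way at 0.736 through Ubb at 0.673.

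**Figure D3:**
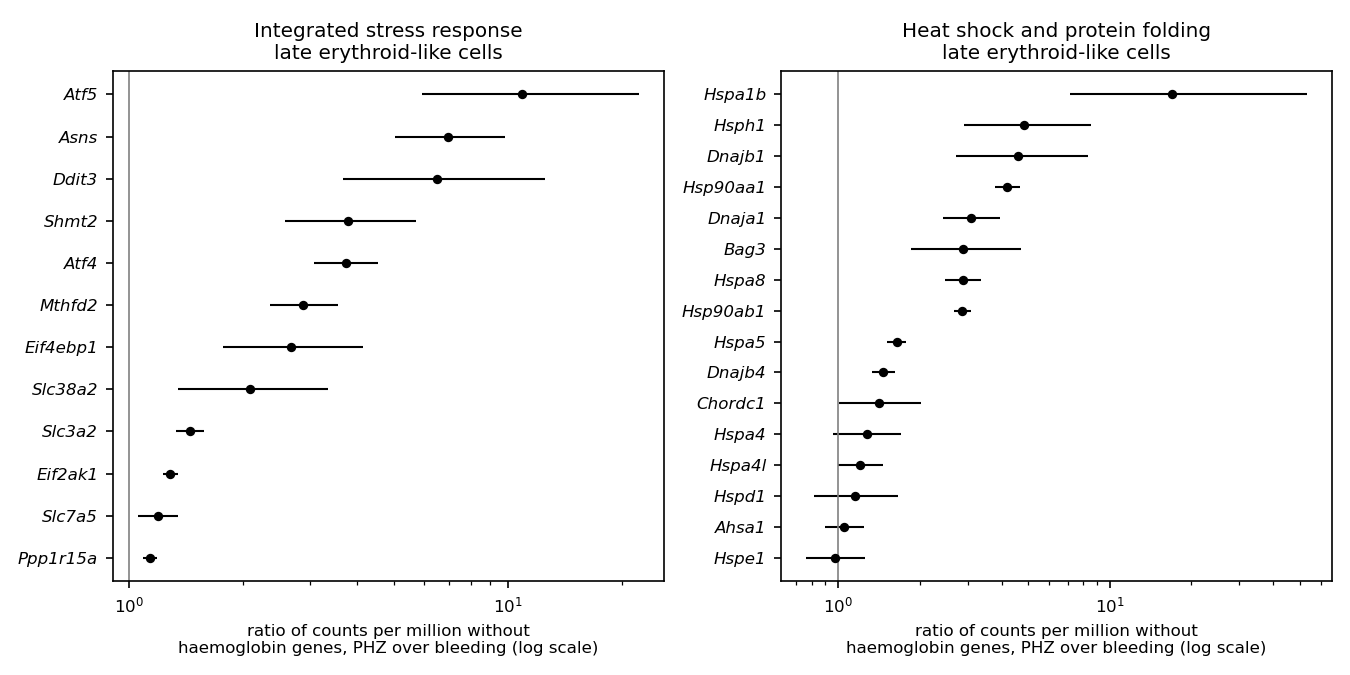
Ratio of CPM without haemoglobin genes, PHZ over bleeding (log scale), in late erythroid-like cells for measured members of the integrated stress response (left) and heat shock (right) lists, with bars for 95% counting intervals. All 12 stress response genes are over 1, from Ppp1r15a at 1.14 to Atf5 at 10.9; Hspa1a, with 0 UMIs in the bleeding library, is left out.

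The monocyte or macrophage-like class was made of different clusters in the 2 libraries, so its genes separated macrophages from monocytes. Cluster 17, monocyte-like, held 154 of the 171 PHZ cells, and clusters 25 and 29, red pulp macrophage-like, held 124 and 88 of the 283 bleeding cells but 17 and 0 PHZ cells. Genes lower in the PHZ library had almost no PHZ UMIs: Ptprm (0 and 1253), Dlc1 (0 and 881), Ank2 (0 and 574), the glutamate transporter gene Slc1a3 (0 and 455), Hs3st2 (0 and 440), the complement gene C6 (0 and 371) and Kcnj16 (0 and 249). Dlg2, Dgki, Itgad, Gfra2 and the haemoglobin scavenger receptor gene Cd163 had 1, 2, 6, 2 and 1 against 1278, 980, 1176, 565 and 374. The Cd163 ratio was 0.00242 (6.11e-05 to 0.0136). Slc40a1, which encodes the iron exporter ferroportin, was at 0.0328 (0.0265 to 0.0401), the complement gene C1qa at 0.0555 and the phagocytic receptor gene Mertk at 0.0175. Higher in the PHZ library, Cd93 was at 10.4 (6.36 to 18.3), Vcan at 6.74 and Clec4e at 5.43, with Spon1, Lilr4b, Ptafr and F10 between 4.15 and 5.10, and S100a11, Ms4a6d, Chil3 and S100a6 between 2.85 and 3.51. Without the 3 highest cells in each library Cd93 was at 16.0 and Spon1 at 13.9 (4.46 to 69.8). The acute phase gene Saa3, with 139 and 3 UMIs, was at 42.0 (14.1 to 206) but turned to a log2 ratio of -0.49 without doublet removal, and 3 PHZ cells held 71.2% of its UMIs.

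The fixed gene lists were compared in this class too. Alarmins and acute phase had a median of 1.36 (19 of 19), with S100a8 at 5.67, and neutrophil secondary and tertiary granule genes moved with it at 0.81 (10 of 10, percentile 99.98). Neutrophil-like cells had a higher share in the PHZ library, and background RNA was not ruled out for their genes. Ribosomal proteins were at 0.44 (80 of 80), and mitochondrially encoded genes at -0.50 (0 of 13), which turned to 0.18 with all UMIs as the denominator. Complement, scavenging and efferocytosis was at -0.71 (10 of 32), with Trem2 at 2.97 and Axl at 0.0363. Iron recycling was at -0.54 (5 of 19), with Spic, the transcription factor gene of red pulp macrophages, at 0.136 and Hmox1, which breaks down haem, at 0.371, but turned to 0.24 with all UMIs as the denominator. Haemoglobin genes took 5.05% of the class UMIs in the PHZ library and 40.8% in the bleeding library, and that denominator shifted the all-gene median by 0.68 (each cell scaled alike, 0.19). It took complement to -0.03, alarmins to 2.04, the neutrophil granule genes to 1.55 and ribosomal proteins to 1.11. The mitochondrially encoded and iron recycling lists stayed below the all-gene median of 0.73 with that denominator. The granule genes were at 1.48 with each cell scaled alike. Alternative activation was at -3.16 (3 of 7), from -1.14 to -4.53 over the alternatives, and its sum was at 0.713. Hypoxia targets were at 0.57 (18 of 25) and glycolysis at 0.73 (14 of 16), with Pkm at 1.90, although the glycolysis sum went the other way at 0.787 through Bpgm at 0.0721, and both medians were further from 0 with all UMIs, 1.19 and 1.41. Red cell genes moved with the macrophages: the red cell membrane list was at -2.05 (2 of 16), down to -3.29 with members of 50 or more CPM, with Slc4a1 at 0.0880. Haem synthesis was at -0.91 (4 of 13), with Alas2 at 0.0591, and the list was at -0.06 with all UMIs. Immediate early genes were at 0.49 (13 of 16), with Klf2 at 1.82 and Nr4a1 at 2.28, and at 1.17 with all UMIs.

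Monocyte-like cells alone, with the red pulp macrophage-like clusters left out, had more RNA of haem and iron handling in the PHZ library. Of the genes below, Hmox1, Spic, C1qa and C1qb are also red pulp macrophage markers. The iron recycling list was at 0.43 (14 of 17, percentile 100), with Hmox1 at 3.45 (2.56 to 4.75), Spic at 6.02 (3.08 to 13.4), and the ferritin genes Fth1 at 1.82 (1.72 to 1.93) and Ftl1 (interval 1.53 to 1.67). Without the 3 highest cells in each library Hmox1 was at 2.75 and Cd93 at 8.56, and Spic at a log2 ratio of 3.53 against 2.59. Vcan was at 3.14, Ptafr at 2.93, Lilr4b at 3.32, Cd93 at 5.49, Adap2 at 6.47 and Frmd4b at 3.48, the last 2 with log2 ratios of 1.65 and 0.72 without doublet removal. C1qa (96 and 1 UMIs) had all its PHZ UMIs in 3 cells, and C1qb was at 9.03, or 0.29 on the log2 scale without doublet removal. Saa3 at 18.2 and Slpi at 3.42 turned to -1.53 and -2.01 there. Interferon genes were lower in the PHZ library. The type I list was at -0.50 (1 of 34, percentile 0), with Ifit3 at 0.238 (0.159 to 0.352) and Irf7, its master regulator, at 0.491 (0.382 to 0.633). Ifi211 was at 0.513, Ifi206 at 0.312, Herc6 at 0.473 and Ifitm3 at 0.824. The log2 ratio of Ifit3 was -2.07, and -3.77 with at least 50 genes. Without the 3 highest cells in each library, Ifit3 was at 0.323 and Ifi206 at 0.436. Irf7 was then at 0.673 (0.498 to 0.915), Herc6 at 0.579 and Ifi211 at 0.563. Hspa1a and Hspa1b, opposite to their direction in late erythroid-like cells, were at 0.174 and 0.102, and the heat shock list had a median of 0.10 (11 of 17) but a mean of -0.25. Pde7b was at 0.440, or 0.639 without the 3 highest cells in each library. Complement genes were at 0.36 (21 of 26), alarmins at 0.37 (15 of 18), with S100a8 at 19.2 (11.4 to 35.3), and the unfolded protein response at 0.39 (22 of 24), with Calr at 1.86. S100a8 is a gene of neutrophil-like cells, whose share was higher in the PHZ library, and it was not among the named genes here. Background RNA was not ruled out for it. MHC class II was at 0.57 (5 of 7), with H2-Ab1 at 2.08, but turned to -0.40 with a minimum of 500 UMIs and -0.16 with at least 50 genes. G2 and M phase was at -0.74 (2 of 34), with Ube2c at 0.384, but turned to 0.40 with at least 50 genes.

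**Figure D4:**
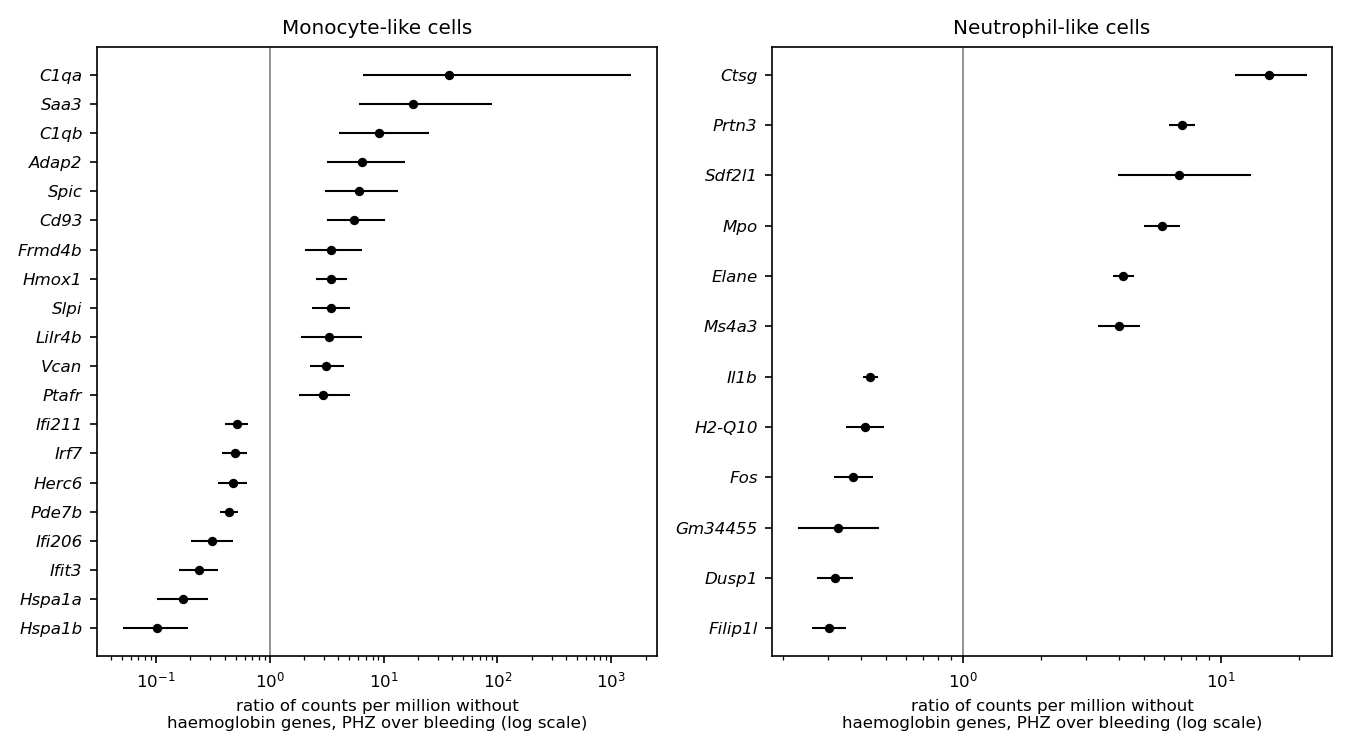
Ratio of CPM without haemoglobin genes, PHZ over bleeding (log scale), for the genes named in monocyte-like cells (left) and neutrophil-like cells (right), with bars for 95% counting intervals. Hmox1 is at 3.45 and Il1b at 0.436; C1qa rests on 3 PHZ cells, Saa3 and Slpi turn direction without doublet removal, and the bleeding UMIs of Ctsg, Mpo, Prtn3 and Elane came almost wholly from 3 cells.

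Neutrophil-like cells of both libraries included precursors. The precursor cluster 31 held 47 of 295 PHZ cells and 11 of 111 bleeding cells. Cluster 22 held the most PHZ cells, 138 against 37, and the mature cluster 23 the most bleeding cells, 63, with 110 in the PHZ library. Primary granule genes, which neutrophils make only early, had a median of 2.31 (8 of 8, percentile 100): Ctsg was at 15.3 (11.3 to 21.4), Prtn3 at 7.05, Mpo at 5.89 and Elane at 4.17. Ms4a3 and the chaperone gene Sdf2l1 (6.87) were also among the named genes higher in the PHZ library. The 3 highest bleeding cells held 100% of the Ctsg and Mpo UMIs there, 97.0% of Prtn3, 99.8% of Elane and 84.6% of Sdf2l1, which was at 23.3 without the 3 highest cells in each library. The list was 0.84 with a minimum of 2000 UMIs, 0.69 with at most 5% mitochondrial UMIs and 1.05 without doublet removal. S phase was at 0.93 (36 of 37), with Pcna at 1.92, ribosomal proteins at 0.58 (77 of 79) and heat shock at 0.80 (12 of 13), with Hspd1 at 3.85. Mitochondrially encoded genes moved with them at 0.42 (13 of 13, percentile 99.5). With at most 5% mitochondrial UMIs these 4 lists were at -0.05, -0.09, 0.18 and -0.09, and without doublet removal the mitochondrially encoded genes were at -0.0014. G2 and M phase was at 0.27 (40 of 47) and the unfolded protein response at 0.73 (21 of 24), with Calr at 3.14. Secondary granule genes were at -0.056 (5 of 16), with Camp at 0.902 and Ngp at 0.786, and turned to 0.21 with each cell scaled alike. Among the genes lower in the PHZ library, Il1b was at 0.436 (0.408 to 0.466), the immediate early genes Fos at 0.375 and Dusp1 at 0.319, H2-Q10 at 0.416 and Gm34455 at 0.328. Il1b and H2-Q10 are leading genes of cluster 23, which held 110 of the 295 PHZ and 63 of the 111 bleeding cells of the class. Filip1l was at 0.302, or 0.822 without the 3 highest cells in each library. The immediate early list, which tissue dissociation also induces, was at -0.75 (1 of 16), with Btg2 at 0.480 and Junb at 0.507. In monocyte-like cells alone it was at -0.26 (3 of 16), opposite to the whole class, and in B and T cell-like cells at 0.049 (8 of 12) and 0.12 (8 of 12). In late erythroid-like cells it was at -0.54 (1 of 6) but turned to 0.24 with all members of 1 or more UMI. Inflammatory cytokines and chemokines were at -0.43 (3 of 10) or -1.37 with at least 50 genes, with 75 and 3 UMIs of Ccl4 (ratio interval 2.31 to 34.7).

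In B cell-like cells, Agbl1 was at 2.43 (2.32 to 2.55), the transcription factor gene Sox5 at 1.97 and Vpreb3, made by B cell precursors and naive B cells, at 1.67. Agbl1 and Vpreb3 are leading genes of cluster 7, which held 327 of the 1447 PHZ and 356 of the 3338 bleeding cells of the class, so its mix of clusters differed. Slc15a2, Myof, Atxn1 and the urokinase receptor gene Plaur were at 0.420, 0.421, 0.579 and 0.585. Marginal zone-like cells (cluster 9), whose markers include Myof, had a ratio of 0.580 (0.458 to 0.729) outside the erythroid-like class, cluster 7 was at 2.17 (1.86 to 2.52) and the follicular-like cluster 1 at 0.920. MHC class II genes were slightly lower, at -0.20 (1 of 10, percentile 0), with Cd74 at 0.881 and H2-Aa at 0.827. Alarmins were at 0.35 (8 of 9), with S100a8 at 2.89, and haem synthesis at 0.34 (12 of 14), with Alas2 at 2.67. These are genes of neutrophil-like and erythroid-like cells, whose shares were higher in the PHZ library. Immunoglobulin constant regions were at 0.12 (6 of 7), with Ighm at 1.21. Activation genes were at 0.072 (12 of 20) with a mean of -0.029. Heat shock was at 0.034 (10 of 15), type I interferon at 0.019 (9 of 16) and the integrated stress response at 0.017 (6 of 10) with a mean of -0.018, all near the 0.036 of all genes.

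Among T cell-like cells, the CD8-like cluster 5 had a ratio of 0.484 (0.403 to 0.577) outside the erythroid-like class, cluster 4 was at 0.537, and cluster 10, with CD4 and regulatory T cell genes, at 0.774. Nav2 at 1.96 (1.72 to 2.22) and Sorcs2, a sorting receptor gene, at 1.89 were the named genes, and none was lower. Naive T cell genes were at -0.10 (4 of 13, percentile 0.32), with the transcription factor gene Lef1 at 0.902 and Satb1 at 0.901, and activation and exhaustion genes at 0.13 (11 of 19), with Maf at 1.53 and Ctla4 at 1.42. Nav2 and Ctla4 are leading genes of cluster 10, which held 111 of the 459 PHZ and 338 of the 1939 bleeding cells of the class. Cytotoxic genes were at 0.16 (6 of 8), with Klrg1, a marker of effector cells, at 4.89 and Ccl5 at 1.52. Alarmins were at 1.27 (6 of 7), with S100a6 at 2.75 and S100a4 at 2.59, or 0.26 after background subtraction, and haem synthesis at 0.27 (11 of 11), with Alas2 at 1.93. MHC class II genes were at -1.44 (1 of 7, percentile 0), with Cd74 at 0.368, H2-Ab1 at 0.270 and H2-Eb1 at 0.181, and between -0.13 and -0.66 under 5 of the alternatives. Their level here was low, at 16.7 and 45.5 CPM for Cd74 against 6782 and 7697 in B cell-like cells, whose share was also lower in the PHZ library. Heat shock at 0.0054 (8 of 15), the integrated stress response at 0.033 (7 of 13, mean -0.027) and type I interferon at -0.057 (8 of 25) were near 0.

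Summed over all cells, the libraries differed as their cell classes did. Granule and alarmin genes of neutrophils were higher in the PHZ library, with Prtn3 at 13.5, Elane at 13.3, Retnlg at 7.15, Mpo at 6.86 and S100a8 at 4.94. Ankrd36, with nearly all of its UMIs in erythroid-like cells, was at 6.96. The 3 highest cells decided the size for Prtn3, Elane and Mpo, at log2 ratios of 6.45, 7.53 and 6.49 without them. Vcam1, an adhesion molecule of red pulp macrophages, was at 0.0545 (0.0470 to 0.0629), and the T cell genes Cd28, Cd6 and Themis at 0.282, 0.295 and 0.311. Gm12840, a leading gene of the T cell-like cluster 4, was at 0.284. Adgrl3, a leading gene of the dendritic cell-like cluster 24, was at 0.234. Alarmins were at 1.85 (19 of 20), haem synthesis at 1.31 (13 of 15), naive T cell genes at -1.14 (0 of 13) and MHC class II at -0.98 (0 of 10), against -0.13 for all genes. This all-gene median shifted by -0.28 with all UMIs, -0.20 with each cell scaled alike and 0.13 under median-of-ratios scaling. Both libraries expressed Y-linked genes (Ddx3y at 76.1 and 83.9 CPM, Uty at 77.9 and 96.5) and held 6 and 1 UMIs of Xist.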

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

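Of the tests below, the one for whole late erythroid cells with macrophages was chosen before its result was seen, and all others after.

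A signal was found in barcodes outside the called cells, above the limit that a count of 0 allows. Barcodes with 1000 or more UMIs but under 300 genes carried 93.8% haemoglobin UMIs in the PHZ library and 94.0% in the bleeding library, over 2618 and 3047 barcodes. The gene minimum left them out, and a minimum of 50 genes takes the erythroid-like ratio from 2.02 to 1.41. Barcodes with at least 200 UMIs but under the minimum of 1000 held the platelet gene Pf4 at 152 CPM in the PHZ library (119 to 192) and 140 in the bleeding library (107 to 181), where 0 counts would allow 6.26 and 7.02. Called cells held Pf4 at 0.393 and 0.258 CPM and the background barcodes at 5.76 and 1.61, so platelet RNA sat below the UMI minimum in both libraries; Ppbp, another platelet gene, was at 37.6 and 74.8.

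Red pulp macrophage-like cells were fewer in the PHZ library. Dilution by erythroid-like cells was argued against by the ratio of 0.189 (0.108 to 0.310) outside that class. Removal by the cell filters was argued against by markers made mostly by these cells, whose median ratio over all barcodes was 0.162 (0.0819 to 0.302, 23 genes). Bursting of the cells in the PHZ suspension was argued against by the same kind of markers in background barcodes, at 0.124 (0.0623 to 0.225, 22 genes). Both marker ratios were scaled to all UMIs without haemoglobin, so erythroid-like RNA also lowers them and part of each value may be dilution. The markers were picked in the bleeding library. What stays open, untested, is loss or retention of the macrophages in the tissue before the suspension, a difference between mice, and an effect of the PHZ treatment, which may be the reason but was not tested by any value here.

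In the bleeding library, red pulp macrophage-like cells held haemoglobin RNA, 48.2% of the UMIs of the median cell, with 144 of 212 cells over 20%. Free RNA in every droplet was argued against: the median of 2823.5 haemoglobin UMIs per cell was 65.7 times that of B cell-like cells, 43. Whole late erythroid cells attached to or inside the macrophages had the values they need: late erythroid transcripts other than haemoglobin came along at 1.34 times (0.905 to 1.77, 27 transcripts) their level per haemoglobin UMI in late erythroid-like cells. This may be engulfment, a main task of these cells, or attachment during preparation, and these counts do not separate them. No effect of treatment was tested, since the PHZ library had 17 such cells. Those had a median of 46 haemoglobin UMIs and 3.16%, with 4 cells over 20%.

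In late erythroid-like cells the members of the integrated stress response and heat shock lists were higher in the PHZ library, with a joint median log2 ratio of 1.52 (0.506 to 1.92, 29 members). Background RNA was argued against by a median of 1.53 (0.529 to 2.25) after its subtraction. Stress from handling, shared by all cells, was argued against by a median of 0.033 (-0.057 to 0.14, 22 members) in B cell-like cells, the higher of the B and T cell-like medians. Only those classes were used. The heat shock median of neutrophil-like cells was also higher in the PHZ library, though less so with the stricter mitochondrial limit. Hspa1a and Hspa1b were lower in monocyte-like cells. Handling stress limited to some classes was not tested. A different mix of clusters and maturity cannot be told apart from a difference within cells: with both libraries weighted alike over 24 strata the median was 1.28, but its interval, 0.218 to 1.74, reached below the bound of 0.25 set for the test. A response of late erythroid cells to PHZ stays open and was not tested, since treatment and library are the same division.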

How the results depend on the processing

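The gene minimum of 50, the shares outside the erythroid-like class, the clusters left out and the 3 cells left out were alternatives chosen after the results were seen. No paired analysis was possible because each group had 1 library. Each alternative value was compared with the interval of the main value, a counting interval for shares and genes and an order-statistic interval over members for lists. A share or list counts as reversed only where that interval excluded no difference, and a gene at any change of sign. Over 29 main results and 315 alternative values, 283 stayed within the interval, 30 moved beyond it and 2 reversed; over 230 other results, 1972 of 2534 stayed within it, 544 moved and 18 reversed. Where the values below differ, the cause was not tested unless given. Small cell numbers widened the intervals of some classes, such as plasma cell-like with 8 PHZ cells and red pulp macrophage-like with 17.

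Ratios of shares moved as follows. Outside the erythroid-like class, where the denominator itself is smaller, ratios were 1.02 for B cell-like (reversed), 0.558 for T cell-like, 6.27 for neutrophil-like, 1.42 for monocyte or macrophage-like, 0.979 for NK cell-like, 1.32 for dendritic cell-like and 5.11 for monocyte-like cells. The B cell-like interval there, 0.960 to 1.09, covers 1. Monocyte or macrophage-like and dendritic cell-like cells also passed 1, but their main intervals, 0.728 to 1.07 and 0.634 to 1.06, already covered it. With a gene minimum of 50, which admits haemoglobin-rich barcodes, they were 1.41 for erythroid-like, 1.18 for dendritic cell-like and 0.753 for plasma cell-like cells, and, of erythroid-like cells, 4.25 for early (1.08 to 1.33 under 6 others, whose intervals cover 1) and 0.929 for late stages; no proliferating precursor cluster was found there. Red pulp macrophage-like cells were at 0.0618 with 2000 UMIs, monocyte-like cells at 2.33 with 500, and proliferating precursor-like cells at 3.05 at resolution 2.

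Log2 medians of lists moved too. With all UMIs as the denominator, which counts haemoglobin, erythroid-like cells were at 0.60 for the integrated stress response, 0.62 for haem synthesis and 0.25 for type I interferon (reversed), late erythroid-like cells at 1.05 for the proteasome, monocyte or macrophage-like cells at 2.04 for alarmins and 0.24 for iron recycling (the other sign, from a main interval of -2.46 to 0.071 that spans 0), B cell-like cells at -0.26 for MHC class II and T cell-like cells at -0.13 for naive genes. With each cell scaled alike, the erythroid-like values were 1.23, 0.55 and 0.19 for the same 3 lists, the last reversed. These scalings shift all genes of a class, to medians of 0.44 and 0.28 in erythroid-like cells, and the interferon list stayed below them. All UMIs shift B and T cell-like genes by -0.064 and -0.035, which alone turns the sign of their stress and type I interferon medians, except the last in T cell-like cells, and of immediate early genes in B cell-like cells. In erythroid-like cells alarmins and complement had too few members with all UMIs. MHC class II in T cell-like cells, at -1.44 over 7 members, was between -0.13 and -0.66 with 500 or 2000 UMIs, at most 5% mitochondrial UMIs, 50 genes or each cell scaled alike. Median-of-ratios scaling gave 0.58 for the late proteasome. A gene minimum of 50 gave 0.76 for the erythroid integrated stress response and, in monocyte-like cells, -1.07 for type I interferon and 0.40 for G2 and M phase (reversed); 500 UMIs gave -0.97 for that interferon list. In neutrophil-like cells S phase was at 0.15 with 2000 UMIs, 0.64 with 500, 0.47 without doublet removal and -0.051 with at most 5% mitochondrial UMIs, where ribosomal proteins were at -0.094, both reversed. Mitochondrially encoded genes reversed there too, at -0.094 with at most 5% mitochondrial UMIs and -0.0014 without doublet removal, and in monocyte or macrophage-like cells, at 0.18 with all UMIs. All UMIs put the all-gene median of the latter class at 0.73, so the list stayed below the other genes.

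Single genes that reversed are given as log2 ratios. Without doublet removal, Saa3 was at -0.49 in monocyte or macrophage-like and -1.53 in monocyte-like cells, and Slpi at -2.01 in the latter. With a gene minimum of 50, Angpt1 was at 2.25 in erythroid-like and 1.46 in early cells, and Cmtm7 at 0.039 in early cells. Prtn3 in early cells was at 1.31 and 1.37 with 500 and 2000 UMIs, 1.21 with up to 20% mitochondrial UMIs, 0.31 with 50 genes and 1.20 without the 3 highest cells.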

Other observations

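All comparisons in this part were chosen after the results were seen, and no tests of explanations were run on them.

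Clusters without a class name held B lineage, interferon-rich and other cells. Cluster 27, with precursor B cell genes, held 86 PHZ cells and 8 bleeding cells, 3.10% and 0.123% of cells outside the erythroid-like class, a ratio of 25.3 (12.3 to 60.6). Cluster 21, with germinal centre genes, held 33 and 165 cells, 1.19% and 2.53%, a ratio of 0.471 (0.314 to 0.688). Cluster 26, with interferon-induced genes, held 20 and 84 cells, a ratio of 0.561 (0.326 to 0.922), and cluster 28 held 17 and 75, a ratio of 0.534 (0.296 to 0.914). Cluster 19, with T cell receptor complex genes, held 66 and 142, a ratio of 1.10 (0.806 to 1.48).

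Of 7904 genes measured in at least 4 classes, 4 differed in 1 direction by over 0.5 on the log2 scale in every class where they were measured, and all 4 were lower in the PHZ library. Cdk5rap1, which modifies mitochondrial transfer RNA, was at a ratio of 0.196 in erythroid-like, 0.136 in monocyte or macrophage-like, 0.296 in B cell-like, 0.314 in T cell-like and 0.121 in neutrophil-like cells. The peptide transporter gene Slc15a2 was at 0.329, 0.174, 0.420 and 0.342 in the first 4 of these and had 14 and 16 UMIs in neutrophil-like cells. The others were Cr2 and Jchain, genes of B and plasma cells.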
